A study of Mus musculus with 38 samples.

How the data were processed

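RNA from 38 mouse samples in 10 groups and 4 experiments was sequenced on an Illumina platform as paired-end reads from a stranded messenger RNA kit, per the labels' protocols. Groups came from the sample titles. In the culture experiment, 3 libraries each came from 4T1 cells left untreated, from 4T1 cells given exosomes of insulin sensitive (IS) adipocytes and from 4T1 cells given exosomes of insulin resistant (IR) adipocytes, for 72 h. In the brain experiment there were 5 control, 5 IS and 5 IR libraries, in the primary tumour experiment 4 control and 5 IR libraries, and in the miRNA experiment 2 libraries titled as a scrambled control and 3 titled as miR-145a-3p. The labels call the samples biological replicates without naming separate cultures or animals, so the p values measure only the spread between these samples, part of which may be technical. In the tumour table the 4th control is named by another number than in its title, and it is called control 4 here.

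The deposited values were expected counts per gene, 1 table per experiment, and each experiment was analysed within its own table. The in vitro and brain tables held expected counts made by the authors with RSEM and the tumour and miRNA tables held estimated counts from salmon, per the file headers and titles. Per the series text, the authors ran an nf-core RNA-seq pipeline and DESeq2 and left out genes with few reads relative to library size. The submitters' processing notes list Trimmomatic, STAR, featureCounts and DESeq2 without versions, and the builds GRCm38, also called mm10, and GRCm39, also called mm39. Which build each table used is not given in the sources used here, so no gene coordinates are printed. Of all values, 97.8% in the in vitro and brain tables, 84.4% in the tumour table and 85.6% in the miRNA table were whole numbers. The counts were not normalised between libraries as deposited. In the in vitro table, 3 columns matched no sample and were not used.

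Expected counts were rounded to whole numbers before testing. Genes in the in vitro and brain tables carried only identifiers. Their symbols were taken by identifier from the table that pairs both, which named 52139 of 55487 genes, and 3257 more were named from a reference gene table, leaving 91 unnamed. The total count per library was 8455412 to 12785398 in the in vitro table, 8790616 to 13272583 in the brain table, 17392887 to 21909370 in the tumour table and 24972592 to 32637552 in the miRNA table. Levels were set in CPM, relative to the summed counts of the tested genes times the scaling factor of the library. The filter below used CPM relative to the total count. Counting intervals cover counting error only.

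Genes were kept at 3 CPM or more in at least 3 libraries of the experiment, after the filter in the series text, which left 10888, 12924, 12962 and 10751 genes in the in vitro, brain, tumour and miRNA tables. Counts were scaled by the trimmed mean of M values and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with all groups of an experiment in the fit and no covariate. The authors' tool, DESeq2 1.42.0, was run as an alternative. The biological coefficient of variation was 0.0576 in the in vitro, 0.159 in the brain, 0.326 in the tumour and 0.0819 in the miRNA experiment. P values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are means of CPM with the standard deviation (SD) over libraries.

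Lists of genes, 43 in all, for pathways, cell types and RNA quality, were fixed before the data were examined, together with the groups, the test designs, the rule for naming genes and the alternatives. Each list with 5 or more measured members was tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the lists of that comparison, and again with an estimated correlation. The p values with an estimated correlation shifted slightly with the order of the design columns, which was fixed. Fry was run as a test of change in either direction. Members were also counted after adjustment over the list alone. The results for lists that passed in no comparison are given for the list of genes associated with brain metastasis and for skeletal muscle. Named genes were the 8 largest rises and the 8 largest falls among called genes with a mean of 10 CPM or more, a symbol that is not a predicted one, and no overlap between the libraries of the groups, up to 4 members with the smallest adjusted p of each list past camera, the 5 genes with the smallest p where none was called, and Insr, Irs1, Cdh1, Vim and Mki67. Genes outside this rule are marked as chosen after their values were seen.

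The test was tried on simulated counts with the means, library sizes and spread of these samples and 200 changed genes. For genes changed by 2-fold it recovered 97% in the comparison of IR with IS in culture, 94% for IR and 98.5% for IS against untreated cells, 89.4% in brain IR against IS, 86.2% in brain IR and 79.7% in brain IS against control, 47% in tumours and 98.5% in the miRNA experiment. For genes changed by 1.5-fold it recovered 4.48% in tumours and 46.9% in brain IR against IS. Of the simulated calls, 2.04% to 7.88% were false. No pair of replicates agreed within counting noise, the lowest chi-square per degree of freedom being 2.19.

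Alternatives were DESeq2, the DESeq2 size factors and upper quartile scaling in edgeR, no filter, filterByExpr, voom with quality weights, only the groups compared, each library left out in turn, and the replicate number as a block where the columns of both groups were matched to numbered samples. Added after seeing the data were fits without tumour libraries that stood apart in immune or muscle transcripts, a fit without mitochondrially encoded genes in the miRNA experiment, random sites matched for G and C, and all sites of similar number. Overlaps of called genes were tested with Fisher's exact test, one-sided, adjusted over the 28 tests with called genes in both lists. For shared controls, 20 simulated groups without change gave the chance value.

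Seed sites were counted in 3' untranslated regions of GENCODE vM21 (GRCm38), a build that may not be that of the table. The region was known for 94% of the genes tested in the miRNA experiment, and genes without one counted as not searched. The mean log2 fold change of genes with and without a site was set against that of 1000 random sites of the same length, as a permutation over sites. The sequence of the miRNA came from general knowledge and not from the labels. On 1 simulated data set this permutation test gave p = 0.597 with no shift and p = 0.002 with a shift. Of 100 further simulated sets, 3 had p under 0.05 with no shift and 100 with a shift. The p values vary with the draw of random sites. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for sites, exact tests and plots. The small RNA content of the exosomes, gene ontology enrichment and patient survival were not analysed here.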

Results

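The series asked how insulin resistance acts on triple-negative breast cancer through exosomes, small vesicles that cells release, from adipocytes. RNA was sequenced from 4T1 cells, a mouse mammary adenocarcinoma line used as a model of this cancer, cultured with exosomes of insulin sensitive (IS) or insulin resistant (IR) 3T3-L1 adipocytes, a mouse fibroblast line that forms fat cells, or without exosomes. Further libraries came from a clonogenic assay on brain, in which tumour cells from a tissue grow as colonies, from primary 4T1 tumours, and from 4T1 cells titled as given miR-145a-3p or a scrambled RNA. The 4 experiments held 9, 15, 9 and 5 libraries, in that order. Library totals ran from 8455412 counts in culture to 32637552 counts in the miRNA experiment. Each experiment was quantified in its own table, so levels in different experiments were set side by side without a test.

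The comparison of cells given IR exosomes with untreated cells asked what these exosomes change in 4T1 cells. Cxcl5, a chemokine that draws neutrophils, was at 261 ± 12.3 CPM with IR exosomes and 8.40 ± 0.785 CPM without (SD, n = 3 each), a 31-fold rise (log2 4.96 ± 0.063, SE, adjusted p = 5.72e-18). Il1a, the cytokine interleukin 1 alpha, rose 21.2-fold (log2 4.41 ± 0.095, adjusted p = 1.24e-14). In the other direction, genes of cholesterol synthesis fell, and Insig1, which holds back the sterol sensor and is itself induced when sterols are low, was 2.67-fold lower (log2 -1.42 ± 0.064, adjusted p = 1.96e-10).

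Among other large rises in IR exosome cells, Cxcl1, another neutrophil chemokine, rose 12.1-fold, C3, the central complement protein, 9.92-fold, and Csf3, the granulocyte growth factor, 5.39-fold. Zc3h12a, a ribonuclease that degrades inflammatory messengers, rose 5.85-fold and Nfkbiz, a nuclear regulator of NF-kB targets, 5.46-fold. For all genes given here and below as the largest changes of a comparison, every library of a group lay above every library of the other group. Lcn2, a secreted protein that binds iron carriers of bacteria, was at 22.4 ± 1.84 CPM against 0.167 ± 0.061 CPM, with 726 counts in the IR exosome libraries and 5 in the untreated ones, a ratio of 135 with a 95% counting interval of 57.6 to 417. In the list of NF-kB and cytokine genes, 11 of 25 members rose and 8 fell (camera adjusted p = 0.00694, 11 and 10 adjusted over the list alone). The adjusted p was 0.108 with an estimated correlation.

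Of 25 cholesterol biosynthesis and uptake genes, 22 fell and 0 rose (median log2 -0.72, camera adjusted p = 2.96e-34, 22 lower adjusted over the list alone, adjusted p = 0.0069 with an estimated correlation). Fdps, Cyp51 and Idi1, enzymes of the sterol pathway, were 2.19-fold, 2.13-fold and 2.05-fold lower. Of 21 fatty acid synthesis genes, 12 fell and 0 rose (median log2 -0.32, camera adjusted p = 1.16e-12, 16 lower and 1 higher adjusted over the list alone, adjusted p = 0.0312 with an estimated correlation). Scd2, a desaturase that makes monounsaturated fatty acids, was at 596 ± 17.4 CPM against 1377 ± 58.6 CPM, and Scd1 was 2.2-fold and Fads2 1.81-fold lower. Fatty acid oxidation genes moved the other way, with 11 of 21 higher and 0 lower (median log2 0.27, camera adjusted p = 1.02e-07, 13 higher and 1 lower adjusted over the list alone, adjusted p = 0.0126 with an estimated correlation). Cpt1a, which controls the entry of fatty acids into mitochondria, went from 19.5 ± 0.902 to 105 ± 2.99 CPM, a 5.36-fold rise (log2 2.42 ± 0.060, adjusted p = 4.69e-14), and Acadl and Slc25a20 both rose 1.57-fold.

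Of 33 genes of the unfolded protein and integrated stress responses, 11 fell and 1 rose in IR exosome cells (median log2 -0.09, camera adjusted p = 0.000572, 12 lower and 1 higher adjusted over the list alone, adjusted p = 0.0312 with an estimated correlation). Asns, which makes asparagine, was 1.51-fold lower, as was Mthfd2, of mitochondrial one-carbon metabolism, and Atf4, the transcription factor of this response, was 1.24-fold lower. Other large falls were in Fgfbp1, a carrier of fibroblast growth factors (3.9-fold), Adamts1, a matrix protease (2.75-fold), Mt2 and Mt1, which bind metals (2.71-fold and 2.33-fold), Thbs1, thrombospondin 1 (2.69-fold), and Zfp469 (2.43-fold). Cdh1, the epithelial adhesion protein E-cadherin, was at 333 ± 6.26 against 453 ± 10.1 CPM (log2 -0.45 ± 0.035, adjusted p = 1.81e-07). Insr, Irs1, Vim and Mki67 did not pass (log2 0.04, -0.23, 0.02 and 0.00, adjusted p = 0.74, 0.159, 0.655 and 0.997). In all, edgeR called 1477 of 10888 genes, 726 higher and 751 lower. Of these 75 were at least 2-fold higher and 25 at least 2-fold lower. The 3 libraries of a group lay wholly apart from the other 3 for 30.2% of genes, against 10% by chance.

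Exosomes of IS adipocytes against untreated cells asked which of these changes also come with exosomes of insulin sensitive fat cells. The most changed genes were largely those named for IR exosomes. Cxcl5 rose 36.6-fold (log2 5.20 ± 0.062, adjusted p = 2.49e-18, n = 3 each), Il1a 22.7-fold, Cxcl1 11.1-fold, C3 10-fold, and Csf3 5.24-fold. Ccl2, a chemokine that draws monocytes, rose 7.56-fold (log2 2.92 ± 0.17, adjusted p = 5.01e-09). Lcn2 had 630 counts against 5, a ratio of 113 with a 95% counting interval of 48 to 348. Insig1 was 3.3-fold lower (log2 -1.72 ± 0.065, adjusted p = 1.35e-11), and Scd2 fell from 1377 ± 58.6 to 475 ± 7.88 CPM.

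With IS exosomes 22 of 25 cholesterol genes fell and 0 rose (median log2 -0.90, camera adjusted p = 3.73e-36, 22 lower adjusted over the list alone, adjusted p = 0.00636 with an estimated correlation). Fdps was 2.97-fold, Cyp51 2.95-fold, Msmo1 2.69-fold and Lss 2.53-fold lower. Fatty acid synthesis had 14 of 21 genes lower and 1 higher (median log2 -0.32, camera adjusted p = 4.4e-12, 15 lower and 1 higher adjusted over the list alone, adjusted p = 0.0364 with an estimated correlation), with Scd1 2.46-fold and Fads2 2.16-fold lower. Fatty acid oxidation had 13 of 21 genes higher and 0 lower (median log2 0.30, camera adjusted p = 1.16e-08, 15 higher and 1 lower adjusted over the list alone, adjusted p = 0.0102 with an estimated correlation), with Cpt1a 4.37-fold and Acadl 1.7-fold higher. NF-kB and cytokine genes had 12 of 25 members higher and 5 lower (median log2 0.19, camera adjusted p = 5.79e-05, 12 and 8 adjusted over the list alone, adjusted p = 0.0364 with an estimated correlation).

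Epithelial genes were lower with IS exosomes, 9 of 22 falling and 2 rising (median log2 -0.19, camera adjusted p = 0.000113, 11 and 2 adjusted over the list alone, adjusted p = 0.062 with an estimated correlation). Cldn4, a tight junction protein, was 1.65-fold, the keratin Krt7 1.53-fold and Krt18 1.4-fold lower. Mesenchymal genes had 6 of 12 members higher and 2 lower (median log2 0.17, camera adjusted p = 0.00242, 8 and 2 adjusted over the list alone, adjusted p = 0.052 with an estimated correlation), with Fn1, fibronectin, 1.27-fold higher. In the extracellular matrix list 12 of 26 rose and 7 fell (median log2 0.13, camera adjusted p = 0.0195, 14 and 7 adjusted over the list alone, adjusted p = 0.0753 with an estimated correlation). Mmp13, a collagenase, rose 3.33-fold (log2 1.74 ± 0.16, adjusted p = 8.79e-07) and Spp1, osteopontin, 1.5-fold, while Mmp9 was 1.33-fold and Adamts1 1.92-fold lower. Of 25 mitosis genes 11 fell and 0 rose (median log2 -0.11, camera adjusted p = 2.57e-06, 15 lower adjusted over the list alone, adjusted p = 0.052 with an estimated correlation), Bub1b, a spindle checkpoint kinase, by 1.22-fold. Ribosomal protein genes had 15 of 53 lower and 0 higher (median log2 -0.08, camera adjusted p = 1.16e-08, 20 lower adjusted over the list alone, adjusted p = 0.255 with an estimated correlation).

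In DNA replication 8 of 29 genes fell and 2 rose with IS exosomes (median log2 -0.04, camera adjusted p = 0.0496, 8 and 2 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation). That call was lost without IS 3 (adjusted p = 0.0934), without control 2 (0.0987) and with upper quartile scaling (0.0633), within a range of 0.0257 to 0.11 over the alternatives. Mcm7, a helicase subunit, was 1.22-fold lower and Ccne1, cyclin E1, 1.68-fold higher. Cdh1 was 1.27-fold lower (log2 -0.34 ± 0.035, adjusted p = 3.59e-06) and Vim, vimentin, 1.09-fold higher (log2 0.12 ± 0.022, adjusted p = 0.00127). Irs1 was 1.26-fold higher (22.8 ± 0.610 against 18.0 ± 0.191 CPM, log2 0.33 ± 0.098, adjusted p = 0.0251). That call was lost without IS 1 (0.053), IS 2 (0.0743), IS 3 (0.0656), control 1 (0.0634), control 2 (0.066) or control 3 (0.0606) and with DESeq2 (0.0569), in a range of 0.00998 to 0.0743. Insr and Mki67 did not pass (adjusted p = 0.743 and 0.416). By edgeR 2101 of 10888 genes were called, 1086 higher and 1015 lower, with 99 at least 2-fold higher and 25 at least 2-fold lower. The libraries of both groups lay wholly apart for 36.8% of genes, against 10% by chance.

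Both comparisons used the same untreated libraries. Among genes called higher, 501 were shared, against 72.4 for independent lists. Among genes called lower, 426 were shared, against 70, and 9 genes were called in opposite directions. The log2 fold changes correlated at 0.796, and at 0.508 in simulated groups without change (covariance 0.0766 and 0.00812). Part of the excess may come from the shared controls, which are too few to split.

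**Figure D1:**
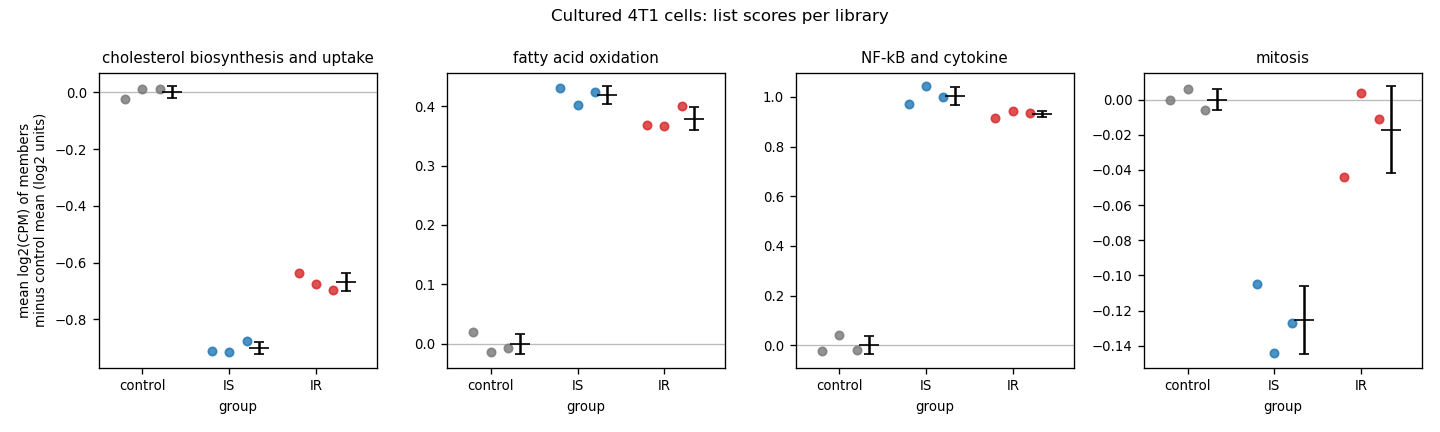
Mean log2 level of 4 gene lists in each library of cultured 4T1 cells, relative to the mean of the untreated libraries (y axis, log2 units), with 1 point per library and bars for the mean and SD of each group (n = 3). Cholesterol genes lay at -0.90 ± 0.022 with IS exosomes and -0.67 ± 0.031 with IR exosomes, and mitosis genes at -0.12 ± 0.020 and -0.02 ± 0.025.

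IR was then compared with IS exosomes. Differences were small (median log2 size 0.25 among called genes). Against untreated cells the cholesterol list fell less with IR (mean log2 -0.67) than with IS exosomes (-0.90). The extracellular matrix list was lower with IR. Both passed camera also with an estimated correlation. Epcam, an epithelial adhesion protein, was at 200 ± 9.80 CPM with IR and 144 ± 8.22 CPM with IS exosomes (SD, n = 3 each), 1.39-fold higher (log2 0.47 ± 0.054, adjusted p = 0.000102), with untreated cells at 179 ± 12.2 CPM. H1f0, a linker histone of cells that leave the cycle, was 1.51-fold higher (log2 0.60 ± 0.048, adjusted p = 6.46e-06), and Stab1, a scavenger receptor, was 2.12-fold lower (log2 -1.08 ± 0.15, adjusted p = 0.00048).

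Cholesterol genes had 12 of 25 members higher and 0 lower with IR than with IS exosomes (median log2 0.23, camera adjusted p = 3.59e-13, 17 higher adjusted over the list alone, adjusted p = 0.0305 with an estimated correlation). Cyp51 was 1.39-fold, Fdps 1.36-fold and Hmgcs1 1.28-fold higher. The extracellular matrix list had 9 of 26 lower and 0 higher (median log2 -0.11, camera adjusted p = 5.72e-06, 12 lower adjusted over the list alone, adjusted p = 0.0277 with an estimated correlation). Adamts1 was 1.43-fold and Mmp9 1.24-fold lower. Of 33 stress response genes 8 were lower and 0 higher (median log2 -0.06, camera adjusted p = 3.97e-05, 11 lower adjusted over the list alone, adjusted p = 0.0277 with an estimated correlation), among them Atf5 by 1.47-fold and Asns by 1.24-fold. Mitosis genes had 7 of 25 higher and 0 lower (median log2 0.09, camera adjusted p = 4.78e-07, 12 and 1 adjusted over the list alone, adjusted p = 0.0517 with an estimated correlation), with Nusap1 1.35-fold and Bub1b 1.17-fold higher. Ribosomal protein genes had 6 of 53 higher and 0 lower (median log2 0.08, camera adjusted p = 2.98e-13, 14 higher adjusted over the list alone, adjusted p = 0.151 with an estimated correlation). NF-kB and cytokine genes had 7 of 25 lower and 0 higher (median log2 -0.06, camera adjusted p = 0.0249, 8 lower and 3 higher adjusted over the list alone, adjusted p = 0.151 with an estimated correlation), including Ptgs2, which makes prostaglandins, 1.27-fold and Cxcl5 1.18-fold lower.

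Further lists passed camera between IR and IS exosomes but lost the call without a library, over alternatives whose range is given. Epithelial genes had 7 of 22 higher and 1 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0249, 0.0725 without IR 2 and 0.0607 without IS 2, range 0.00755 to 0.253, adjusted p = 0.253 with an estimated correlation), Krt18 by 1.27-fold and Krt8 by 1.22-fold. DNA replication had 4 of 29 higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0249, 0.0987 without IR 3, range 0.0157 to 0.126, adjusted p = 0.126 with an estimated correlation). Fatty acid synthesis had 4 of 21 higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0294, 0.0699 without IR 3 and 0.11 without IS 2, range 0.00987 to 0.363, adjusted p = 0.363 with an estimated correlation), with Scd2 1.25-fold and Fads2 1.2-fold higher. Immediate early genes had 1 of 19 higher (2 adjusted over the list alone, camera adjusted p = 0.0301, 0.192 without IR 1 and 0.11 without IS 2, range 0.00571 to 0.327, adjusted p = 0.327 with an estimated correlation). No circadian clock gene of 15 was called over all genes or adjusted over the list alone (median log2 -0.16, camera adjusted p = 0.0249, 0.0921 without IR 2 and 0.0519 without IS 2, range 0.0105 to 0.126, adjusted p = 0.126 with an estimated correlation). The 13 mitochondrially encoded genes had a median log2 of -0.64 with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.00496, 0.642 without IR 2, range 1.74e-06 to 0.642, adjusted p = 0.472 with an estimated correlation).

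Larger single differences were the falls of Slco4a1 (1.96-fold), Col12a1 (1.92-fold), Wnt10a (1.82-fold), Atp1b1 (1.76-fold) and Ass1, of arginine synthesis (1.65-fold, adjusted p = 2.94e-05), and the rises of Ccng2 (1.55-fold), Slc39a10, a zinc transporter (1.42-fold), and Ung, a DNA repair glycosylase (1.4-fold). Irs1, an adaptor of the insulin receptor, was 1.48-fold lower with IR than with IS exosomes (15.4 ± 2.15 against 22.8 ± 0.610 CPM, log2 -0.57 ± 0.099, adjusted p = 0.00316), with untreated cells between them at 18.0 ± 0.191 CPM. Vim was 1.07-fold lower (log2 -0.10 ± 0.022, adjusted p = 0.0145), but 0.0849 without IR 2 and 0.0577 without IS 3 (range 0.00574 to 0.0849). Insr, Cdh1 and Mki67 did not pass (adjusted p = 0.506, 0.0967 and 0.491). By edgeR 683 of 10888 genes were called, 307 higher and 376 lower, with 2 at least 2-fold higher and 5 at least 2-fold lower. The libraries lay wholly apart for 26.6% of genes, against 10% by chance. The number of called genes was 871 without IR 1, 376 without IR 2, 384 without IR 3, 362 without IS 1, 378 without IS 2 and 295 without IS 3.

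The brain libraries held transcripts that cultured 4T1 cells lacked. Epcam was at 2.00 ± 0.983 CPM in control, 0.979 ± 0.963 in IS and 0.913 ± 0.475 in IR brain libraries (SD, n = 5 each), against 179 ± 12.2 CPM in untreated cultured cells (n = 3). Xist, the RNA of the inactive X chromosome in female cells, was at 276 to 660 CPM in the 15 brain libraries and at most 0.0895 CPM in the exosome culture experiment. Pecam1, an endothelial adhesion protein, was at 12.4 to 200 and at most 0.310 CPM, in that order. These tables were quantified separately.

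Brain IR against control libraries asked what differs in the brain samples titled IR, whose titles name no treatment. By camera the endothelial list was higher in IR and the macrophage list lower. Neither passed with an estimated correlation (adjusted p = 0.262 and 0.372). Pecam1 was at 159 ± 43.1 against 18.8 ± 4.13 CPM (SD, n = 5 each), an 8.49-fold rise (log2 3.09 ± 0.40, adjusted p = 0.000409). Dll4, a Notch ligand of growing vessels, rose 23.5-fold (log2 4.55 ± 0.69, adjusted p = 0.000868) and Cldn5, a tight junction protein of brain vessels, 10.2-fold. Itgam, the integrin CD11b of myeloid cells, was at 9.12 ± 5.59 against 43.5 ± 5.57 CPM, 4.79-fold lower (log2 -2.26 ± 0.54, adjusted p = 0.0133).

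Of 19 endothelial genes 18 rose and 0 fell in brain IR (median log2 2.07, camera adjusted p = 7.83e-19, 18 higher adjusted over the list alone, adjusted p = 0.262 with an estimated correlation). Ptprb rose 9.77-fold, Clec14a 9.54-fold, Erg 9.39-fold and Ly6c1 8.81-fold. Of 17 macrophage genes 14 fell and 0 rose (median log2 -1.44, camera adjusted p = 2.56e-10, 17 lower adjusted over the list alone, adjusted p = 0.372 with an estimated correlation). C1qc, a complement component, was 4.68-fold, Csf1r, the receptor for macrophage growth factor, 3.03-fold and Spi1, a myeloid transcription factor, 2.7-fold lower. Clec7a, Megf6 and Lat2 were also among the largest falls, at 3.79-fold, 3.66-fold and 3.6-fold. Of 17 fibroblast and pericyte genes 3 fell and 1 rose (median log2 -0.42, camera adjusted p = 0.00572, 6 and 1 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation), with Thy1 3.12-fold and Col5a2 2.04-fold lower.

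Stem cell associated genes had 6 of 16 higher and 1 lower in brain IR (median log2 0.21, camera adjusted p = 0.00572, 6 and 1 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation). They were Kit (11.2-fold), Cd24a (2.33-fold), Prom1 (2.29-fold) and Notch1 (1.85-fold) among others, of which Notch1 is also expressed by endothelial cells. Fatty acid oxidation had 10 of 26 higher and 0 lower (median log2 0.19, camera adjusted p = 0.000353, 11 and 1 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation), with Cpt1b 1.86-fold higher. Glycolysis had 7 of 21 higher and 0 lower (median log2 0.17, camera adjusted p = 0.00115, 8 and 2 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation), with Pfkp, a phosphofructokinase, 1.6-fold higher. Replication-dependent histone genes had 3 of 7 lower and 0 higher (median log2 -0.56, camera adjusted p = 0.00203, 5 lower adjusted over the list alone, adjusted p = 0.262 with an estimated correlation), H3c4 by 2.34-fold. Targets of p53 had 3 of 20 lower and 1 higher (median log2 -0.15, camera adjusted p = 0.0187, 4 and 2 adjusted over the list alone, adjusted p = 0.262 with an estimated correlation), with Ccng1 1.28-fold lower and Ddit4l 1.94-fold higher.

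Immediate early genes, switched on within minutes by growth factors, had 8 of 21 lower and 1 higher in brain IR (median log2 -0.16, camera adjusted p = 0.0234, 8 and 5 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation). Fos was at 21.9 ± 5.09 against 67.5 ± 8.43 CPM, 3.09-fold lower (log2 -1.63 ± 0.15, adjusted p = 4.1e-05), and Zfp36 was 2.21-fold lower. That list lost its call without IR 4 (adjusted p = 0.0853) and without control 5 (0.0522), in a range of 0.00879 to 0.372 over the alternatives. Microglia genes had 2 of 5 lower (median log2 -0.69, camera adjusted p = 0.0433, 3 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation) and lost the call without IR 3 (0.0602), IR 4 (0.0674), control 1 (0.051), control 4 (0.0578) or control 5 (0.0715), in a range of 0.018 to 0.372. Oligodendrocyte genes had 3 of 9 higher (median log2 0.46, camera adjusted p = 0.0433, 4 adjusted over the list alone, adjusted p = 0.63 with an estimated correlation) and lost the call without IR 1 (0.132), IR 4 (0.0791) or control 1 (0.0913), in a range of 0.00777 to 0.63.

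Vim was 1.37-fold lower in brain IR than in control libraries (log2 -0.45 ± 0.11, adjusted p = 0.0124), while Insr, Irs1, Cdh1 and Mki67 did not pass (adjusted p = 0.106, 0.307, 0.668 and 0.751). By edgeR 1514 of 12924 genes were called, 833 higher and 681 lower, with 266 at least 2-fold higher and 195 at least 2-fold lower. The count was 836 without IR 3, 956 without control 2 and 898 without control 4. The libraries of the groups lay wholly apart for 11.8% of genes, against 0.794% by chance.

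Brain IS against control libraries asked the same of the brain samples titled IS. By camera the endothelial and interferon response lists were higher in IS and the immediate early list lower, with 9 of 19, 11 of 28 and 7 of 21 members called. None of these 3 lists passed with an estimated correlation (adjusted p = 0.379, 0.194 and 0.194). Pecam1 was at 72.4 ± 54.3 CPM against 18.8 ± 4.13 CPM (SD, n = 5 each), 3.86-fold higher (log2 1.95 ± 0.39, adjusted p = 0.00841). IS 2 carried part of this rise, with Pecam1 at 162 CPM there and 23.8 to 80.6 CPM in the other IS libraries. Without IS 2 the log2 was 1.43 (adjusted p = 0.0127, range over the alternatives 0.000435 to 0.026). Ier2, an immediate early gene, was 3.04-fold lower (log2 -1.60 ± 0.17, adjusted p = 9.39e-05) and Fos 2.87-fold lower (log2 -1.52 ± 0.14, adjusted p = 4.67e-05). Lox, which links collagen fibres, fell from 910 ± 79.0 to 330 ± 40.6 CPM (2.76-fold, log2 -1.46 ± 0.17, adjusted p = 0.000195).

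Interferon response genes had 11 of 28 higher and 0 lower in brain IS (median log2 0.58, camera adjusted p = 9.85e-11, 12 higher adjusted over the list alone, adjusted p = 0.194 with an estimated correlation). Xaf1 was 2.63-fold, Irf1, an interferon-induced transcription factor, 1.6-fold and Parp14 1.51-fold higher. Genes of MHC class I presentation had 3 of 15 higher and 0 lower (median log2 0.27, camera adjusted p = 0.000149, 6 higher adjusted over the list alone, adjusted p = 0.194 with an estimated correlation). Of 19 endothelial genes 9 rose and 0 fell (median log2 1.21, camera adjusted p = 1.99e-06, 14 higher adjusted over the list alone, adjusted p = 0.379 with an estimated correlation), among them Cldn5 (4.81-fold), Clec14a (3.79-fold) and Esam (2.31-fold). Immediate early genes had 7 of 21 lower and 0 higher (median log2 -0.27, camera adjusted p = 5.36e-05, 9 lower adjusted over the list alone, adjusted p = 0.194 with an estimated correlation), with Zfp36 2.13-fold and Junb 1.6-fold lower.

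Astrocyte genes had 5 of 13 higher and 0 lower in brain IS (median log2 0.45, camera adjusted p = 5.36e-05, 7 higher adjusted over the list alone, adjusted p = 0.267 with an estimated correlation), among them S100b, a calcium binding protein (2.05-fold), Sparcl1 (2.01-fold) and Gja1, a gap junction protein (1.68-fold). Oligodendrocyte genes had 3 of 9 higher and 0 lower (median log2 0.62, camera adjusted p = 0.00092, 5 higher adjusted over the list alone, adjusted p = 0.379 with an estimated correlation), with Cnp, a myelin enzyme, 1.4-fold higher. Fatty acid oxidation had 3 of 26 higher and 0 lower (median log2 0.17, camera adjusted p = 5.36e-05, 4 higher adjusted over the list alone, adjusted p = 0.379 with an estimated correlation), with Cpt1b 1.76-fold higher. Targets of p53 had 3 of 20 lower and 1 higher (median log2 -0.17, camera adjusted p = 0.00958, 7 and 1 adjusted over the list alone, adjusted p = 0.194 with an estimated correlation), with Pmaip1, which promotes cell death, 1.52-fold lower. Fibroblast and pericyte genes had 4 of 17 lower and 1 higher (median log2 -0.23, camera adjusted p = 0.00958, 5 and 1 adjusted over the list alone, adjusted p = 0.393 with an estimated correlation), with Fbln2 2.08-fold lower. Replication-dependent histone genes had 3 of 7 lower and 0 higher (median log2 -0.37, camera adjusted p = 0.0108, 3 lower adjusted over the list alone, adjusted p = 0.267 with an estimated correlation).

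Another 3 lists passed camera in brain IS and lost the call without several libraries. Glycolysis had 2 of 21 higher and 0 lower (median log2 0.06, 2 higher adjusted over the list alone, camera adjusted p = 0.0349, adjusted p = 0.571 with an estimated correlation), but 0.106 without IS 1, 0.0979 without IS 5, 0.112 without control 1 and 0.0811 without control 2 (range 0.0147 to 0.571). Mitochondrially encoded genes had 0 of 13 called over all genes or adjusted over the list alone (median log2 0.25, camera adjusted p = 0.0299, adjusted p = 0.571 with an estimated correlation), but 0.0914 without IS 2, 0.0552 without IS 3, 0.0519 without IS 4 and 0.206 without control 2 (range 0.00615 to 0.571). Mitosis genes had 0 of 25 called over all genes or adjusted over the list alone (median log2 0.26, camera adjusted p = 0.0497, adjusted p = 0.699 with an estimated correlation), but 0.128 without IS 1, 0.203 without IS 2, 0.1 without IS 3, 0.125 without control 2 and 0.0694 without control 5 (range 0.00728 to 0.699).

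Further large changes in brain IS were the rises of Tyrp1, a melanin enzyme (7.68-fold), Egfl7, a vessel protein (3.73-fold), Strip2 (2.79-fold) and Slc26a7 (2.72-fold), and the falls of Svep1 (2.96-fold), Erfe, a hormone of iron balance (2.83-fold), Ccn5 (2.79-fold), Enho (2.52-fold) and Wnt2b (2.51-fold). Insr, Irs1, Cdh1, Vim and Mki67 did not pass (adjusted p = 0.43, 0.0641, 0.533, 0.258 and 0.908). By edgeR 835 of 12924 genes were called, 435 higher and 400 lower, with 118 at least 2-fold higher and 47 at least 2-fold lower. The count was 465 without control 2, 488 without control 3, 498 without control 4 and 524 without control 5. The libraries lay wholly apart for 7.81% of genes, against 0.794% by chance.

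Brain IR and IS libraries were compared with the same controls. Among genes called higher 255 were shared, against 28 for independent lists. Among genes called lower 196 were shared, against 21.1, with 0 in opposite directions. With the controls split between the comparisons, 27.1 genes higher and 42.4 genes lower were shared on average, against 1.48 and 1.29 for independent lists. The log2 fold changes correlated at 0.696, and at 0.513 in simulated groups without change (covariance 0.111 and 0.0196).

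**Figure D2:**
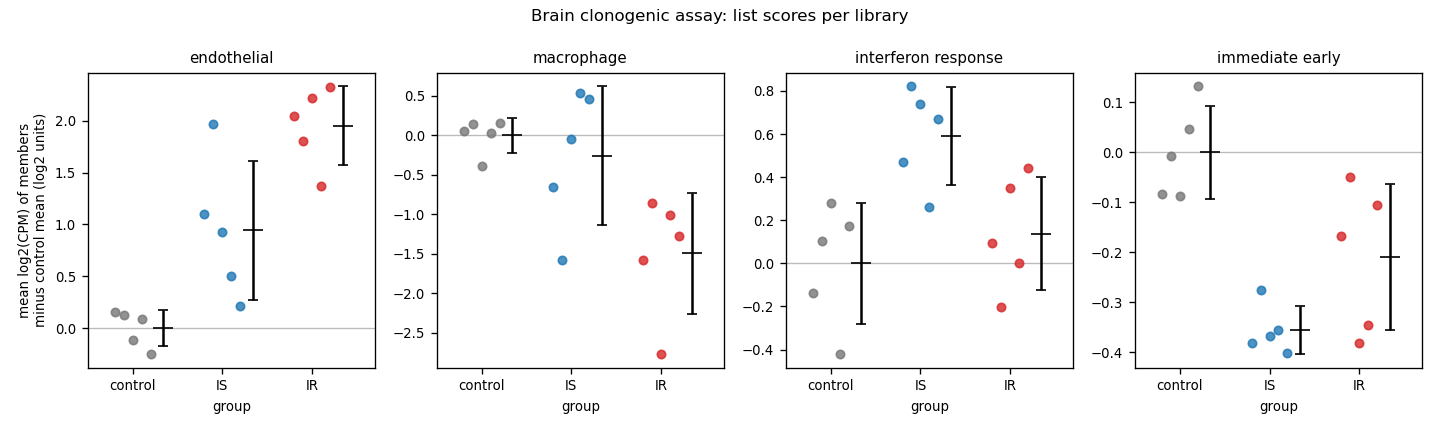
Mean log2 level of 4 gene lists in each brain library, relative to the mean of the control libraries (y axis, log2 units), with 1 point per library and bars for the mean and SD of each group (n = 5). Endothelial genes lay at 1.95 ± 0.38 in IR and 0.94 ± 0.67 in IS libraries, where single libraries ran from 0.21 to 1.97, and macrophage genes at -1.49 ± 0.76 and -0.26 ± 0.87.

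The direct comparison of brain IR with IS libraries called few single genes. Cemip2, a cell surface hyaluronidase, was 1.5-fold higher (log2 0.58 ± 0.087, adjusted p = 0.024, n = 5 each), Rsrp1, an arginine and serine rich protein, 1.68-fold lower (log2 -0.75 ± 0.11, adjusted p = 0.024) and Pkdcc, a secreted kinase, 1.46-fold lower (log2 -0.54 ± 0.088, adjusted p = 0.0379). These and Pde10a were among 6 called genes, 3 higher and 3 lower, of 12924 tested by edgeR. The count was 3 without IR 1, 0 without IR 2, 0 without IR 3, 145 without IR 4, 2 without IR 5, 200 without IS 1, 1139 without IS 2, 0 without IS 3, 0 without IS 4 and 1 without IS 5. At an unadjusted p of 0.05 it was 2344, and DESeq2 called 604. The libraries lay wholly apart for 1.89% of genes, against 0.794% by chance.

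Gene groups differed between brain IR and IS with no member called over all genes. Endothelial genes had a median log2 of 0.98, with 18 of 19 higher adjusted over the list alone (camera adjusted p = 1.48e-14, adjusted p = 0.341 with an estimated correlation). Macrophage genes had a median log2 of -1.26, with 17 of 17 lower adjusted over the list alone (camera adjusted p = 9.72e-12, adjusted p = 0.341 with an estimated correlation). Interferon response genes had a median log2 of -0.43, with 2 of 28 lower adjusted over the list alone (camera adjusted p = 7.23e-09, adjusted p = 0.341 with an estimated correlation), and MHC class I genes -0.20, with 4 of 15 lower adjusted over the list alone (camera adjusted p = 0.000384, adjusted p = 0.341 with an estimated correlation). Microglia genes had a median of -0.82, with 4 of 5 lower adjusted over the list alone (camera adjusted p = 0.00725, adjusted p = 0.341 with an estimated correlation). Astrocyte genes had -0.27 with 3 of 13 lower adjusted over the list alone (camera adjusted p = 0.00919, adjusted p = 0.512 with an estimated correlation) and adipocyte genes -0.28 with 3 of 9 lower adjusted over the list alone (camera adjusted p = 0.0267, adjusted p = 0.341 with an estimated correlation). Hypoxia response genes had 0.14 with 4 of 20 higher adjusted over the list alone (camera adjusted p = 0.00566, adjusted p = 0.341 with an estimated correlation) and heat shock genes 0.12 with 0 of 14 called adjusted over the list alone (camera adjusted p = 0.00566, adjusted p = 0.512 with an estimated correlation).

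Stem cell associated genes had a median log2 of 0.13 between brain IR and IS, with 4 of 16 higher adjusted over the list alone (camera adjusted p = 0.0234, 0.0732 without IR 1 and 0.0807 without IS 1, range 0.00761 to 0.505, adjusted p = 0.505 with an estimated correlation). Insulin and IGF signalling genes had 0.10, with 3 of 36 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0234, 0.0515 without IR 4 and 0.297 without IS 1, range 0.00759 to 0.512, adjusted p = 0.512 with an estimated correlation). Among these Insr had a log2 of 0.35 ± 0.086 (adjusted p = 0.0756) and Igf1 of -1.79 (adjusted p = 0.0774). Irs1, Cdh1, Vim and Mki67 did not pass either (adjusted p = 0.452, 0.886, 0.242 and 0.688).

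**Figure D3:**
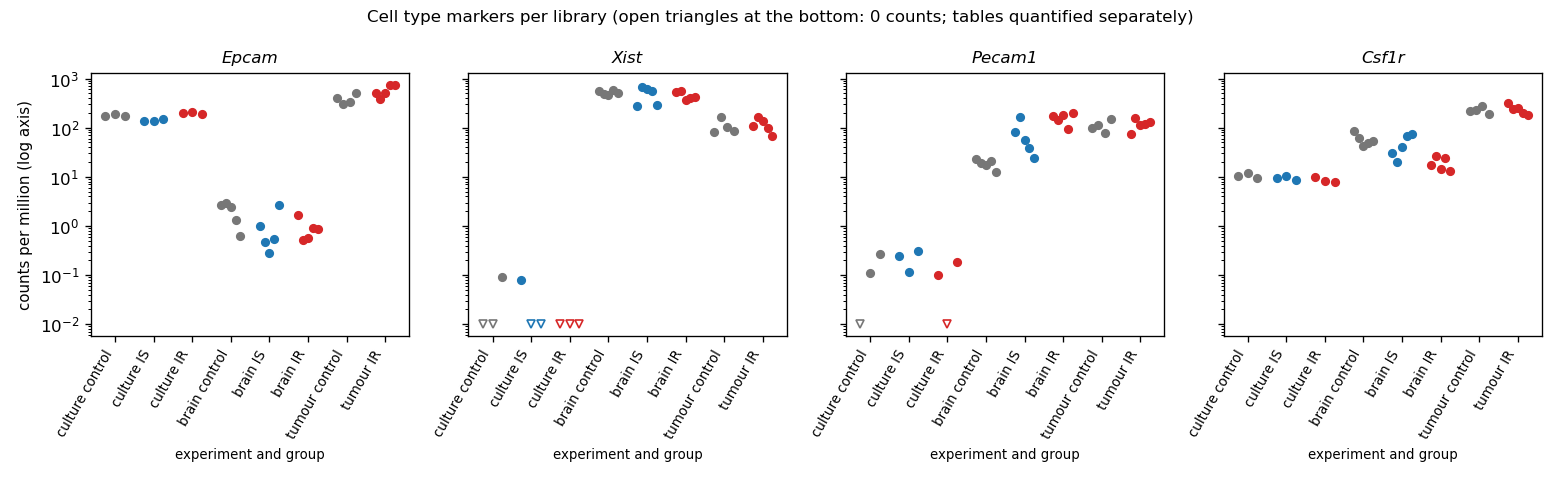
CPM of marker genes in each library of the exosome culture, brain and tumour experiments (y axis, log scale), with 1 point per library. Epcam was at 0.279 to 2.91 CPM in the brain libraries and Xist at 276 to 660 CPM, against at most 0.0895 CPM of Xist in the exosome culture experiment.

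Primary tumours of the IR group were compared with control tumours. Their titles give only IR or control and not how the animals or cells were treated. No gene passed in edgeR, which left 0 of 12962 called, with 991 at an unadjusted p of 0.05 and a smallest adjusted p of 0.354, while DESeq2 called 124, 96 higher and 28 lower. Lamb3, a laminin chain of the basement membrane, was at 83.1 ± 19.3 CPM in IR (SD, n = 5) and 31.9 ± 5.86 CPM in control tumours (n = 4), with a log2 of 1.38 ± 0.20 (adjusted p = 0.354, range over the alternatives 2.73e-07 to 0.813). Lama3, another laminin chain, had a log2 of 1.58 ± 0.25 (adjusted p = 0.354). Csn3, a milk casein, had a log2 of -2.81 ± 0.43 (adjusted p = 0.354). Without IR 4 the count was 1, Ltf, the milk protein lactoferrin, with a log2 of -2.95 (adjusted p = 0.00194, against 0.369 with all libraries, range over the alternatives 0.000127 to 1).

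Some gene groups differed between the tumours by camera while no member was called over all genes. Extracellular matrix genes had a median log2 of 0.42, with 13 of 33 higher adjusted over the list alone (camera adjusted p = 8.9e-10, adjusted p = 0.498 with an estimated correlation). Fibroblast and pericyte genes had 0.65, with 8 of 22 higher adjusted over the list alone (camera adjusted p = 4.19e-08, adjusted p = 0.73 with an estimated correlation). Interferon response genes had 0.23, with 0 of 40 called adjusted over the list alone (camera adjusted p = 1.08e-06, adjusted p = 0.759 with an estimated correlation). Mammary luminal and milk genes had -0.84, with 4 of 10 lower adjusted over the list alone (camera adjusted p = 3.41e-05, adjusted p = 0.11 with an estimated correlation). Epithelial genes had 0.45, with 4 of 21 higher adjusted over the list alone (camera adjusted p = 0.000192, adjusted p = 0.759 with an estimated correlation). Insulin and IGF signalling genes had 0.17, with 1 of 35 higher adjusted over the list alone (camera adjusted p = 0.00398, adjusted p = 0.745 with an estimated correlation). Skin epidermis genes had -1.30, with 4 of 6 lower adjusted over the list alone (camera adjusted p = 0.0077, adjusted p = 0.759 with an estimated correlation). Col1a1, a fibrillar collagen chain, was at 3904 ± 1080 against 1925 ± 564 CPM with a log2 of 1.02 (adjusted p = 0.452), and Tnc, tenascin C, had a log2 of 1.57 (adjusted p = 0.369).

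IR 4 and IR 5 were the tumours high in Acta1, the actin of skeletal muscle, at 4458 and 794 CPM against at most 66.4 CPM elsewhere. With both left out, a choice made after seeing the data, the adjusted p was 0.133 for epithelial, 0.055 for fibroblast and pericyte and 0.0618 for skin genes, in ranges over the alternatives of 7.52e-08 to 0.759, 1.76e-13 to 0.73 and 0.000347 to 0.759. The skeletal muscle list itself did not pass (median log2 4.80, 15 genes, camera adjusted p = 0.143). Control 2 and IR 2 were high in Ighm, an immunoglobulin chain, at 414 and 580 CPM, and IR 5 was at 99.2 CPM, against at most 15.05 CPM in the other tumours. Without control 2 and IR 2, but with IR 5 kept, edgeR again called 0 genes.

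The other lists past camera in tumours lost the call without a library, and none had more than 4 members called over the list alone. Mesenchymal genes (median log2 0.20, 4 of 20 higher adjusted over the list alone, camera adjusted p = 0.00495, adjusted p = 0.498 with an estimated correlation) had 0.101 without IR 5 and 0.0634 without control 2. Endothelial genes (0.25, 0 of 19, camera adjusted p = 0.00134, adjusted p = 0.759 with an estimated correlation) had 0.0713 without IR 5. TGF-beta response genes (0.19, 0 of 24, camera adjusted p = 0.00573, adjusted p = 0.759 with an estimated correlation) had 0.0654 without IR 1 and 0.121 without control 2. Cholesterol genes (-0.12, 0 of 26, camera adjusted p = 0.0105, adjusted p = 0.759 with an estimated correlation) had 0.353 without IR 1 and 0.2 without control 4. Macrophage genes (-0.10, 2 of 23 lower, camera adjusted p = 0.0292, adjusted p = 0.759 with an estimated correlation) had 0.109 without IR 3, 0.233 without IR 4, 0.0984 without control 1 and 0.172 without control 3. Immediate early genes (0.20, 0 of 23, camera adjusted p = 0.0295, adjusted p = 0.759 with an estimated correlation) had 0.16 without IR 1, 0.091 without IR 2, 0.124 without IR 5 and 0.182 without control 3. MHC class II genes (0.32, 0 of 8, camera adjusted p = 0.0443, adjusted p = 0.759 with an estimated correlation) had 0.297 without IR 2, 0.247 without IR 5, 0.377 without control 1, 0.172 without control 3 and 0.0798 without control 4. Glycolysis genes (0.06, 0 of 21, camera adjusted p = 0.0477, adjusted p = 0.759 with an estimated correlation) had 0.769 without IR 1, 0.306 without IR 5, 0.238 without control 2 and 0.0527 without control 3. Adipocyte genes (0 of 19, camera adjusted p = 0.0259 downward, adjusted p = 0.866 with an estimated correlation) had a median log2 of 0.02 but a mean of -0.04, with 0.909 without IR 1, 0.194 without IR 4, 0.238 without control 2 and 0.0527 without control 3. The highest adjusted p over the alternatives was 0.498 for mesenchymal, 0.769 for glycolysis, 0.909 for adipocyte and 0.759 for each of the others.

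Cdh1, Insr, Irs1, Vim and Mki67 did not pass in tumours (adjusted p = 0.923, 0.949, 0.789, 0.897 and 0.998). The libraries lay wholly apart for 2.41% of genes, against 1.59% by chance.

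In the miRNA experiment the titles and the library names of the columns contradict each other as to which libraries received miR-145a-3p, so directions below are of the libraries titled miR-145a-3p against those titled scramble. By camera the mitochondrially encoded list was lower in the titled miR-145a-3p libraries and the cholesterol list higher. Neither passed with an estimated correlation (adjusted p = 0.551 for each). The share of counts from mitochondrially encoded genes was 1.97%, 1.78% and 1.71% in titled miR-145a-3p and 8.59% and 12.5% in titled scramble libraries. mt-Co3, a subunit of cytochrome oxidase, was 8.71-fold lower (log2 -3.12 ± 0.26, adjusted p = 0.000111, n = 3 and 2) and mt-Atp6, of ATP synthase, 6.25-fold lower (log2 -2.64 ± 0.081, adjusted p = 7.84e-06). Scd1 was 3.31-fold higher (log2 1.73 ± 0.099, adjusted p = 4.94e-05), and Scd2 was at 1009 ± 78.7 against 355 ± 35.9 CPM.

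All 13 mitochondrially encoded genes were lower in the titled miR-145a-3p libraries (median log2 -2.71, camera adjusted p = 1.29e-08, 13 lower adjusted over the list alone, adjusted p = 0.551 with an estimated correlation). Cholesterol genes had 23 of 25 higher and 0 lower (median log2 0.83, camera adjusted p = 7.71e-10, 23 and 1 adjusted over the list alone, adjusted p = 0.551 with an estimated correlation), with Hmgcs1 2.53-fold, Fdps 2.33-fold and Idi1 2.27-fold higher. Fatty acid synthesis had 15 of 21 higher and 2 lower (median log2 0.44, camera adjusted p = 5.87e-05, 15 and 2 adjusted over the list alone, adjusted p = 0.551 with an estimated correlation), with Fads2 2.04-fold and Acaca 2-fold higher. Mitosis had 21 of 25 higher and 1 lower (median log2 0.43, camera adjusted p = 1.7e-06, 21 and 1 adjusted over the list alone, adjusted p = 0.551 with an estimated correlation), with Bub1b 1.72-fold, Kif11 1.67-fold and Aurka 1.5-fold higher. Interferon response genes had 20 of 24 lower and 1 higher (median log2 -0.80, camera adjusted p = 1.71e-06, 20 and 1 adjusted over the list alone, adjusted p = 0.551 with an estimated correlation), with Oasl2 2.98-fold, Gbp3 2.52-fold and Rigi, a sensor of viral RNA, 1.76-fold lower. MHC class I had 10 of 17 lower and 0 higher (median log2 -0.41, camera adjusted p = 0.00074, 11 lower adjusted over the list alone, adjusted p = 0.551 with an estimated correlation), with H2-T23 2.35-fold and B2m 1.62-fold lower.

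Ribosomal protein genes had 24 of 53 lower and 3 higher in the titled miR-145a-3p libraries (median log2 -0.23, camera adjusted p = 0.00287, 24 and 3 adjusted over the list alone, adjusted p = 0.833 with an estimated correlation), but 0.125 without scramble 2 (range 4.01e-08 to 0.833). Insulin and IGF signalling had 16 of 29 higher and 1 lower (median log2 0.18, camera adjusted p = 0.0068, 16 and 1 adjusted over the list alone, adjusted p = 0.551 with an estimated correlation), but 0.0501 without scramble 2 (range 0.000308 to 0.551), with Pik3cb 1.49-fold higher and Trib3, an inhibitor of Akt, 1.74-fold lower. Oxidative phosphorylation had 24 of 45 lower and 6 higher (median log2 -0.23, camera adjusted p = 0.0416, 24 and 6 adjusted over the list alone, adjusted p = 0.799 with an estimated correlation), but 0.202 with filterByExpr, 0.0748 without miR-145a-3p library 2, 0.0559 without library 3 and 0.0672 without scramble 2 (range 0.00311 to 0.799). Ndufb3 was 1.89-fold lower and Atp5f1a 1.76-fold higher.

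Other large differences of the titled miR-145a-3p libraries were the rises of Chtf8 (4.26-fold), Pcdhgc3 (3.57-fold), Lrch4 (3.41-fold) and Idh1, which makes NADPH in the cytosol (2.88-fold), and the falls of Rab26os (7.93-fold) and Ankmy1 (7.82-fold). Pcdhgc3 shares exons with its gene cluster and Rab26os lies beside Rab26, so their counts are uncertain. Mki67, the 1 called member of the mitosis list that was lower, was at 594 ± 23 against 677 ± 54.6 CPM (log2 -0.19 ± 0.071, adjusted p = 0.0493). That call was lost without miR-145a-3p library 1 (0.0869), 2 (0.124) or 3 (0.205), without scramble 1 (0.145), with the DESeq2 size factors (0.0585), without a filter (0.563) and with filterByExpr (0.191), in a range of 0.000845 to 0.563. Cdh1, Insr, Vim and Irs1 did not pass (adjusted p = 0.374, 0.925, 0.505 and 0.517). By edgeR 6093 of 10751 genes were called, 3008 higher and 3085 lower, with 109 at least 2-fold higher and 378 at least 2-fold lower. The libraries lay wholly apart for 73% of genes, against 20% by chance, and with mitochondrially encoded genes left out, a choice made after seeing the data, 6097 genes were called.

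**Figure D4:**
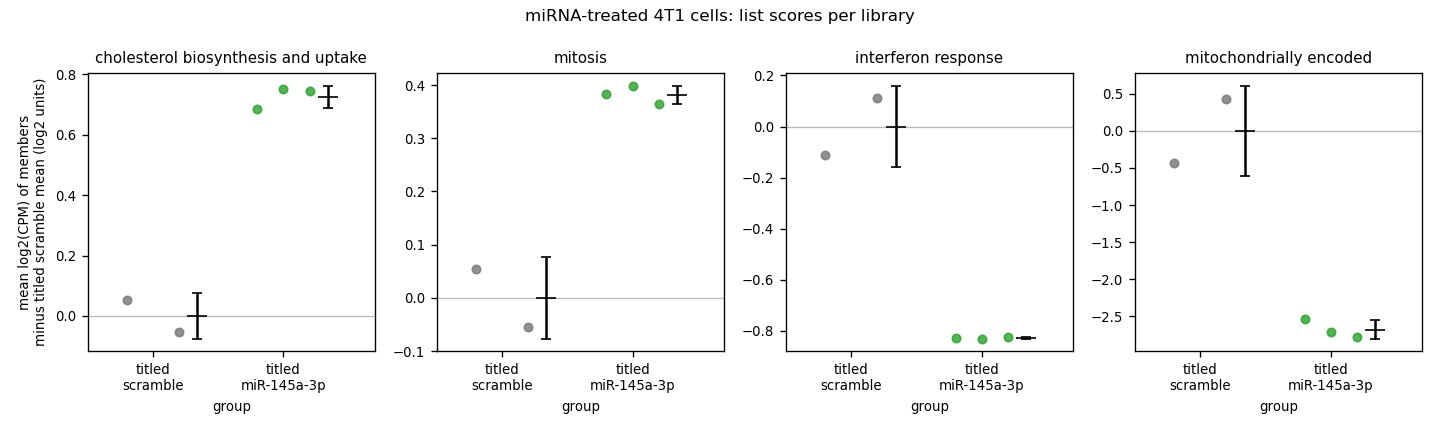
Mean log2 level of 4 gene lists in each library of the miRNA experiment, relative to the mean of the titled scramble libraries (y axis, log2 units), with 1 point per library and bars for the mean and SD of each group (n = 3 and 2). Cholesterol genes lay at 0.73 ± 0.036, interferon response genes at -0.83 ± 0.003 and mitochondrially encoded genes at -2.68 ± 0.12 in the titled miR-145a-3p libraries.

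Genes whose 3' untranslated region holds a 7mer seed site of miR-145a-3p, 1929 in number, had a mean log2 fold change 0.11 above that of the 8180 genes without, while random sites gave a mean of 0.08 (permutation over random sites, p = 0.148). The 8mer site gave a difference of 0.13 (permutation over random sites, p = 0.00799). In culture the 7mer difference between IR and IS exosomes was -0.01 (permutation over random sites, p = 0.34).

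Called genes were compared across experiments, which share no libraries. Genes higher with IR exosomes and in brain IR, each against its control, numbered 76 of 10348 tested in both, against 36.2 for independent lists (Fisher's exact adjusted p = 2.86e-09). Lower in both were 36 against 27.7 (adjusted p = 0.16). Opposite directions passed too, 42 against 26.6 (adjusted p = 0.0095) and 61 against 37.8 (0.000711). The overlap thus does not show a shared response. For IS exosomes and brain IS, 40 were higher in both against 26.2 (adjusted p = 0.0168), 27 lower in both against 26.1 (adjusted p = 0.845), and 47 higher in culture and lower in brain against 27.2 (adjusted p = 0.000711). Another 14 were lower in culture and higher in brain, against 25.1 (adjusted p = 1). Spearman's rho of the log2 fold changes across genes, which are not independent replicates, was -0.00106 for IR and 0.0626 for IS. The brain metastasis list passed camera in no comparison. Its adjusted p was 0.538 for brain IR against IS, 0.953 for brain IR and 0.885 for brain IS against control. It was 0.959 for IR against IS exosomes, 0.598 for IR and 0.23 for IS exosomes against untreated cells, 0.744 in tumours and 0.767 in the miRNA experiment.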

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

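The tests of cell content in the brain libraries, of an exchange of brain IS 2 and IR 4, of the agreement of the 2 titled scramble libraries and of sites matched for G and C were chosen only after the results were seen. A library stood apart from the rest of its group in 17 of 236 groups of values, where chance gives about 1 in 20.

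Of mean log2 list levels, MHC class I was at 4.95 in brain IS 2 (others 5.10 to 5.15), macrophage at 5.49 in brain control 3 (5.92 to 6.04), microglia at 3.92 in brain IR 3 (4.64 to 4.80) and mitochondrially encoded at 8.77 in brain control 2 (9.20 to 9.34). In tumours the cholesterol list was at 5.57 in control 4 (5.32 to 5.36) and the immediate early list at 4.89 in IR 3 (5.33 to 5.42).

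Of single genes in brain control libraries, Mki67 was at 30.9 CPM in control 1 (18.2 to 21.3), Dll4 at 1.63 CPM in control 4 (0.704 to 0.852), Fos at 81.9 CPM in control 5 (59.8 to 65.8) and Ccn5 at 168 CPM in control 3 (86.8 to 93.8). In brain IS 2, Ptprb was at 138 CPM (17.3 to 50.1), Ly6c1 at 27.5 CPM (3.62 to 7.25) and Pgm5 at 19.0 CPM (5.65 to 9.21), and in brain IS 5 Strip2 was at 102 CPM (66.2 to 75.1). In brain IR 3, Ly6c1 was at 52.0 CPM (12.1 to 19.6) and Lox at 180 CPM (363 to 437). Cdh1 in tumours was at 312 CPM in control 4 (152 to 167).

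Changes in list levels differed between experiments in 5 of 9 permutation tests of the difference (adjusted p = 0.0281 each). IR against control in brain minus that in tumours was -0.38 on the log2 scale for immediate early (-0.21 against 0.17), -1.34 for macrophage (-1.49 against -0.15), 1.67 for endothelial (1.95 against 0.28) and -1.03 for fibroblast and pericyte genes (-0.40 against 0.62). IS against control in culture minus that in brain was -0.33 for mitosis genes (-0.13 against 0.21).

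The brain libraries held little Epcam. Cultured 4T1 cells that lost epithelial transcripts are argued against by the macrophage list, of which 12 members reached 10 CPM or more in the brain group with the fewest. Host cells may be a source. Xist at 275.6 CPM or more in each library argues against 4T1 cells alone. Fewer macrophages in IR libraries alone would raise all other cells alike. Yet the endothelial minus the fibroblast and pericyte median was 2.49 (log2). Its 95% interval, 1.68 to 3.13 over 10000 resamples of members, leaves out library spread. A biological effect of the IR or IS group on these cells stays open and was not tested.

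Brain IS 2 had endothelial transcripts at the level of IR libraries, and of 100 splits of the brain IR and IS libraries 6 gave as many genes as the 6 called, so chance is not excluded. The highest other split, which exchanges IS 2 with IR 4, called 1613 against the 6, which points to a structure of the samples. On an axis from the IS mean at 0 to the IR mean at 1 of the other 8 libraries, IS 2 lay at 0.832 and IR 4 at 0.475, beside 0.681 to 1.25 for the other IR and -0.218 to 0.55 for the other IS libraries when each was placed. An exchange could account for this, but IR 4 lay barely on the IS side and the pair was picked as the highest split. With the exchange, 2686 genes in place of 1514 would be called for IR against control and 628 in place of 835 for IS against control. Endothelial content alone cannot be told apart from other causes. It would shift the other cell types alike, and the macrophage shift minus that of fibroblasts and pericytes, from the other libraries of the group, was -1.39 in IS 2 and 0.311 in IR 4. The other libraries reached from -1.15 to 0.921 in IS and from -0.915 to 0.922 in IR. IS 2 lay outside that range by less than the SD of the other IS libraries, a margin required only after the value was seen. An earlier test, with 1061 genes called after the exchange among those not following the endothelial score, was set aside, because the pair was picked for its calls. A spread in response among the samples was not tested.

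For the libraries titled miR-145a-3p and scramble, the 2 scramble libraries agreed less than the others, with a chi-square per degree of freedom of 48.5 against 5.13 to 6.55. A single deviating scramble library is argued against, since their differences from different titled miR-145a-3p libraries correlated at 0.743 or more across genes, in all 6 choices. Without either, 5859 genes or more were called, but a group of 1 borrows the other group's smaller spread. Exchanged titles cannot be told apart from correct ones: genes with a 7mer seed site differed by 0.106, and a permutation over random sites gave p = 0.148, short of the bound set for an exchange. The 8mer, with 0.134 (permutation p = 0.00799), and random sites matched for G and C (permutation p = 0.0392 for the 7mer and 0.0179 for the 8mer) went in the direction that an exchange predicts. These p values vary with the draw of random sites. Transcript length bias cannot be told apart either, with Spearman's rho of 0.26 between fold change and transcript length across genes, between the bounds set for and against it. An effect of the miRNA itself stays open and was not tested.

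Splits of the 6 libraries of each comparison in culture were too few for a share under 0.05, with the real split alone (1) giving as many genes. The real counts were 683, 1477 and 2101 for IR against IS, IR against control and IS against control, and the highest others 1, 1 and 0. In brain, chance is unlikely but not excluded, as only 1 of 100 splits each, the real one, gave as many genes. The counts were 1514 for IR against control and 835 for IS against control, and the highest others 2 and 1. In tumours the real split called 0 genes, so all 100 of 100 splits had to give at least as many, and the splits say nothing about chance. The highest other gave 11.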

How the results depend on the processing

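The fits without tumour IR 4 and IR 5, without tumour control 2 and IR 2 or without mitochondrially encoded genes, the sites matched for G and C and all sites of similar number were chosen only after the results were seen. Of 7225 alternatives for 460 results on named genes, 6794 kept their side of the threshold. Another 239 no longer passed, 192 newly passed and 0 passed reversed. Of 1128 for 87 lists, 959 still passed, 169 did not and 0 reversed. Where a value moved, the cause was not tested.

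With an estimated correlation the lists past the threshold were 3 for IR against IS and 4 for IS against control in culture, and 0 in all 3 brain comparisons, in tumours and in the miRNA experiment. Brain IR against IS called 604 genes with DESeq2, 334 without a filter, 1138 with voom and quality weights and 0 with only both groups in the fit. Voom called 2272 in brain IR against control (1481 shared with the 1514) and 1585 in IS against control (778 shared with the 835). In tumours DESeq2 called 124 genes, and without IR 4 and IR 5 edgeR called 1 gene and 10 lists passed. With genes taken at an unadjusted p, 17 of 36 overlap tests between experiments passed, against 8 of 28 with called genes. Genes changed in the same direction by IR and IS, each against control, then numbered 1733 against 927 in culture and 1456 against 451 in brain.

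Leaving out each library in turn gave 295 to 871 called genes for IR against IS, 1067 to 1402 for IR against control and 1498 to 1688 for IS against control in culture. In brain it gave 0 to 1139, 836 to 1803 (1807 without IS 2) and 465 to 872 in the same order, in tumours 0 to 1 and in the miRNA experiment 4698 to 6888, where a lone scramble library was assumed to vary like the other group. Lists past the threshold ran from 8 to 12, 5 to 6 and 9 to 11 in culture, 11 to 14, 9 to 13 and 10 to 14 in brain, 11 to 18 in tumours and 6 to 10 in the miRNA experiment.

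With the replicate number as a block 513 genes were called in brain IS against control (446 shared), 1 in tumours (Lamb3, adjusted p = 0.0481, range over the alternatives 2.73e-07 to 0.813), 3990 in the miRNA experiment (3962 shared) and 2092 in culture IS against control. Deviations of same-numbered libraries from their group means correlated at -0.21, 0.077 and -0.10 in culture, -0.037 to 0.10 in brain, 0.14, 0.76, 0.20 and 0.081 in tumours and -0.14 and -0.061 in the miRNA experiment. The best partner carried the same number for 1 of 3 libraries in culture, 0 of 5 in brain and 2 of 4 in tumours (2 and 3). The labels name no shared source, so the numbers were not taken as pairs. No paired analysis was possible for comparisons with IR in culture and in brain because the numbered names of those columns match the labels of more than 1 sample, so the numbers serve here only as names of the columns.

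For seed sites, the 8mer gave 0.134 (permutation p = 0.00799), and random sites with the same G and C gave p = 0.0392 for the 7mer difference of 0.106 and p = 0.0179 for the 8mer difference of 0.134. Against all sites of similar number in place of 1000 random ones, the permutation p was 0.134 for the 7mer and 0.0048 for the 8mer, and with the same G and C 0.0311 and 0.00245. In culture none passed (0.355 to 0.759). The direction, higher in the titled miR-145a-3p libraries, is opposite to repression of targets by the miRNA if the titles hold. In simulated tumour counts, 47% of 2-fold and 4.48% of 1.5-fold changes were recovered.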

Other observations

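The exosome lists were measured in all experiments, and some genes that stood out in culture were abundant elsewhere. Lcn2, at 0.167 CPM in untreated cultured cells, was at 87.5 ± 25.1 CPM in control (SD, n = 5), 115 ± 30.6 in IS and 92.7 ± 22 CPM in IR brain libraries, and at 217 ± 88.3 CPM in control (n = 4) and 360 ± 160 CPM in IR tumours (n = 5). Thbs1 was at 640 ± 14.1 CPM in untreated cells (n = 3), 342 ± 11.5 with IS and 238 ± 6.20 CPM with IR exosomes, and at 4015 ± 186 CPM in brain control, 2235 ± 462 in brain IS and 2056 ± 481 CPM in brain IR libraries. In tumours it was at 383 ± 178 CPM in IR (n = 5) and 176 ± 29.3 CPM in control (n = 4), and at 940 ± 34.3 CPM in the titled miR-145a-3p (n = 3) and 486 ± 68.8 CPM in the titled scramble libraries (n = 2). The tables were quantified separately. These genes were chosen after their values were seen.

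Called genes of the exosome and miRNA experiments overlapped as well. Genes lower with IR exosomes than in untreated cells and higher in titled miR-145a-3p libraries numbered 394, against 213 if independent (Fisher's exact adjusted p = 4.48e-46). The reverse were 217 against 187 (adjusted p = 0.0168). Genes higher with IR than with IS exosomes and higher in the titled miR-145a-3p libraries numbered 143, against 86.5 (adjusted p = 3.21e-11), while 109 were lower in both against 101 (adjusted p = 0.427), 120 lower and higher against 103 (adjusted p = 0.083) and 45 higher and lower against 84.8 (adjusted p = 1). No overlap of the called genes of brain IR against control with these libraries passed (smallest adjusted p = 0.0561). With lists at an unadjusted p under 0.05, 452 were higher in both against 391 if independent (Fisher's exact adjusted p = 0.00017). For brain IR against IS, where chance is not excluded, such lists shared 491 higher and 340 lower in both, against 304 and 207. Genes are not independent, so no p value here measures sample spread. Spearman's rho across genes was -0.161 between IR exosomes against untreated cells and the titled miR-145a-3p libraries, 0.0858 for IR against IS exosomes, 0.246 for brain IR against IS and 0.0367 for brain IR against control with the same libraries. The sense of these overlaps turns around if the titles of the miRNA experiment are exchanged.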
